A study of Macaca mulatta with 6 samples.

How the data were processed

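The series holds RNA sequencing of 6 rhesus monkey iPSC libraries in 3 groups of 2, male naive, female naive and male primed. Groups and library numbers came from the sample titles and the gender label. Per the labels' protocols, feeder cells were removed and total RNA was extracted before Illumina sequencing. Reads were aligned with TopHat 1.3.0, per the submitters' processing notes. The genome build, the annotation release and the quantifier's version are not given in the sources used here, so coordinates are those of the deposited files. The files have the layout of Cufflinks gene tracking tables, per the file headers.

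The values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), computed by the authors within each library and deposited with lower and upper bounds and a status for each of 30246 Ensembl rhesus gene rows, per the file headers. No scaling between libraries is stated. Symbols came from the files for 22292 rows, and 15769 identifiers were found in a table of gene names, which alone named 728. Each file has 1 row per identifier, and the same symbol on several rows was resolved in gene lists by the row with the highest mean. An FPKM of exactly 0 is given only as listed at 0.

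The files give no counts. The bounds lie 2 SD either side of FPKM, so the fragments behind a value can be estimated as the square of 2 times FPKM over the distance to the upper bound, called effective fragments here. Of values under 50 effective fragments, 56.5% to 62.6% per library were whole within 0.05. The sums per library were 1754857 and 1478692 in male naive, 8294782 and 10013491 in female naive and 9970137 and 7607125 in primed libraries, a ratio of 6.77 between the deepest and the shallowest. Median effective fragments per tested gene were 40 and 33.2 in male naive and 179 to 225.1 in the other libraries. Rows spanning under 300 bp held 22.3% and 24.4% of the FPKM in male naive, 16% and 11.7% in female naive and 9.3% and 14.9% in primed libraries. These estimates cover counting error only.

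Rows with FPKM of 1 or more in at least 2 libraries and no failed status were tested: 13685 rows, 12106 with a symbol, with 40 rows left out for status. Limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with a mean per group, moderated with a trend (3 residual degrees of freedom), and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Differences are on the log2(FPKM + 1) scale, which understates the change of low genes. The comparisons were naive of both sexes against primed, male naive against male primed, and female against male naive, and all tests are two-sided. The labels call the libraries separate lines but do not tie them to donors, so p-values measure the spread between these lines.

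Lists were tested with limma's camera, with a preset correlation of 0.01 and again with an estimated one, and adjusted over the 26 lists with 3 or more tested members of 28 fixed before the data were examined. These were general pluripotency, naive-associated, primed-associated, LIF and STAT3 response, WNT and beta-catenin targets, FGF and ERK targets, AP-1 and immediate early, Nodal and TGF-beta, BMP response, DNA methylation and demethylation, Polycomb and histone modifiers, glycolysis, oxidative phosphorylation, cholesterol synthesis, G1-S and cell cycle, p53 targets, unfolded protein and ATF4 response, imprinted, epithelial and mesenchymal, reprogramming factors, and markers of neural, mesoderm, endoderm, trophoblast, germ and fibroblast cells. Some lists share members, so their results are not independent. General pluripotency and Nodal and TGF-beta share TDGF1 and GDF3, and FGF and ERK targets share FOS, EGR1, FOSL1 and IER3 with AP-1 and immediate early. Reprogramming factors share POU5F1, SOX2, NANOG and LIN28A with general pluripotency. The X inactivation center and Y-linked lists had too few tested members. The genes named were fixed by a rule in the same way: per comparison, the 10 largest rises and 10 largest falls with a symbol among called genes whose groups do not overlap and whose mean FPKM is 5 or more in the higher group, up to 4 members with the smallest p of each list described, and a fixed set of naive and primed marker genes in any case. Some genes that the rule gave are not reported here. Genes outside the rule are said to be chosen after their values were seen.

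The fit was tested on simulated data, with 50 of 13685 genes changed at each of log2 differences 1, -1, 2 and -2. For naive against primed it recovered 25, 20, 48 and 37 of 50, for male naive against male primed 16, 10, 44 and 25, and for female against male naive 12, 11, 43 and 32. Of 13465 unchanged genes 16, 43 and 53 were called, or 10.2%, 30.3% and 33.8% of the calls. Of unchanged genes with a mean of 20 or more effective fragments 0, 0 and 4 were called. A changed list of 20 genes was called with the preset correlation in all 3 comparisons, and with an estimated correlation at adjusted p = 0.0393, 0.0405 and 0.051, and 0 of 25 unchanged lists was called. The genes were simulated without correlation between them, so this does not show how the preset correlation serves lists of co-regulated genes. Every gene was given the same SD between replicates, 0.153 on the log2 scale, the median of rows with many fragments in every library. The rates of recovery and of false calls may therefore not hold for genes or groups that vary more between lines.

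Alternatives were the pseudocount (0.1 and 0.01), no filter and FPKM of 5, upper-quartile, quantile and median-of-ratios scaling, eBayes robust or without trend, the replicate number as a block, fits to the compared groups, sex ignored, a log2 difference of 1 or more, failed rows kept and each library left out. Added after seeing the data were precision weights, a filter on 10 effective fragments, rows under 300 or 1500 bp left out, libraries thinned to the lowest total, both male naive libraries left out and a crossed block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.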

Results

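RNA was sequenced from 6 induced pluripotent stem cell (iPSC) lines made from rhesus monkey fibroblasts. Of these lines 4 were kept in a naive medium, 2 male and 2 female, and 2 male lines were kept in the primed state. Primed cells resemble the epiblast after implantation and naive cells the earlier epiblast, and the series set out to compare these states. The naive medium held 15% serum replacement, 4 ng/ml bFGF, 10 ng/ml LIF and inhibitors of GSK3 (CHIR99021, 3 µM), MEK (PD0325901, 0.5 µM), p38 (SB203580, 10 µM) and JNK (SP600125, 10 µM). Primed lines were grown in 20% serum replacement with bFGF. Each group had n = 2 libraries, so every SD given here is over 2 lines. The male naive libraries were the shallowest, at 1754857 and 1478692 effective fragments (estimated from the deposited error bounds), against 8294782 and 10013491 for female naive and 9970137 and 7607125 for primed libraries. Depth is therefore confounded with the male naive group, and a low-expressed gene is measured less precisely there. The labels do not say which lines share a donor.

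Libraries of 1 group resembled each other more than libraries of other groups. Pearson's r over the 13685 tested genes (across genes, which are not independent replicates) was 0.953 within male naive, 0.962 within female naive and 0.95 within primed lines. Between groups it ran from 0.915 to 0.921 for male against female naive, 0.903 to 0.921 for male naive against primed and 0.878 to 0.917 for female naive against primed. The first principal component held 39.4% of the variance. The second, with 28.7%, set the male naive libraries (42.96 and 48.27) apart from the other 4 (-16.39 to -31.55).

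Naive lines of both sexes had higher levels of POU5F1 and NANOG than primed lines. POU5F1 (ENSMMUG00000015688, chromosome 4, 30733290 to 30739471), the OCT4 transcription factor, was at 554 ± 24.7 FPKM in male naive, 949 ± 298 in female naive and 122 ± 17.9 in primed lines. NANOG (ENSMMUG00000032158, chromosome 11, 8088932 to 8095022) was at 29.7 ± 1.45, 84.9 ± 15.6 and 1.51 ± 0.815 FPKM in the same order. SPP1 (ENSMMUG00000008793, chromosome 5, 80941184 to 80948955), which encodes the secreted protein osteopontin, had the largest rise among called genes with a symbol, groups that did not overlap and a mean of 5 FPKM or more in the higher group, from 24.7 ± 18.6 FPKM in primed to 572 ± 30.3 in male and 2120 ± 371 in female naive lines. CRABP1 (ENSMMUG00000009393, chromosome 7, 57382094 to 57390538), a retinoic acid-binding protein of the neural list, fell from 521 ± 160 FPKM in primed to 57.7 ± 4.32 in male and 15.6 ± 6.69 in female naive lines. SOX2 was not called, at 118 ± 5.18, 92.9 ± 10.7 and 132 ± 11.8 FPKM (log2 difference -0.34, SE 0.12, adjusted p = 0.119).

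Of 19 tested members of the general pluripotency list, 11 rose and 0 fell (14 and 1 adjusted over the list alone), with a median log2 difference of 1.73 (camera adjusted p = 2.53e-07, adjusted p = 0.344 with an estimated correlation). NANOG rose by 4.39 on the log2(FPKM + 1) scale (SE 0.23, adjusted p = 0.00238), TDGF1, a Nodal co-receptor, by 4.8 (SE 0.26, adjusted p = 0.00254), POU5F1 by 2.55 (SE 0.2, adjusted p = 0.00507) and DPPA4 by 2.47 (SE 0.16, adjusted p = 0.00348). TERF1, a telomere-binding protein, rose by 1.84. Naive-associated genes gave a mixed picture: 5 of 13 tested members rose and 0 fell (5 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.125). NR5A2 rose by 2.03 (SE 0.32), TFAP2C by 1.73 (SE 0.25), KLF5 by 1.61 (SE 0.27) and ZFP42 by 1.08 (SE 0.2). KLF4 stayed under the threshold (log2 difference -0.7, adjusted p = 0.099), as did KLF2 (-0.02, adjusted p = 0.982). KLF17 was listed at 0 in all 6 libraries, and TFCP2L1, ESRRB, TBX3, DPPA3 and DPPA5 did not reach 1 FPKM in 2 libraries and were not tested. A listing at 0 is not evidence of absence: TPI1, a glycolytic enzyme that every cell uses, and LIN28A, both chosen after their values were seen, were also listed at 0 in every library.

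The FGF and ERK target list was higher in naive lines, whose medium held a MEK inhibitor: 12 of 19 members rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 1.63 (adjusted p = 1.07e-05, adjusted p = 0.443 with an estimated correlation). SPRY4, a feedback inhibitor of the pathway, rose by 3.95 (SE 0.48), MYC by 3.22 (SE 0.34), IL17RD by 1.76 (SE 0.17) and DUSP6, an ERK phosphatase, by 1.08 (SE 0.17), while the receptor EPHA4 fell by 1.53 (SE 0.19). ETV4, an ETS factor, rose by 3.89 (SE 0.55). In the Nodal and TGF-beta list 8 of 19 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 1.42 (adjusted p = 0.00146, adjusted p = 0.344 with an estimated correlation). CTGF rose by 2.71 (SE 0.32) and SKIL by 1.84 (SE 0.17), and FST fell by 0.67. AP-1 and immediate early genes rose in 4 of 19 cases and fell in 0 (8 and 0 adjusted over the list alone, adjusted p = 0.0088, adjusted p = 0.483 with an estimated correlation). The 4 were CYR61 (2.05), IER2 (0.76), FOSL1 (2.03) and IER3 (3.01), the last 2 also counted among the FGF and ERK targets. Without primed 1 the adjusted p of this list was 0.0868 and IER3 was at 1.84.

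Neural and ectoderm markers were lower in naive lines: 0 of 12 rose and 5 fell (3 and 8 adjusted over the list alone), with a median of -1.30 (adjusted p = 0.0088, adjusted p = 0.483 with an estimated correlation). Besides CRABP1 (-4.06, SE 0.28), ZNF521 fell by 2.08, NCAM1 by 1.84 and the neuronal microtubule gene MAP2 by 1.39. Of 15 imprinted genes 1 rose and 3 fell (2 and 6 adjusted over the list alone; adjusted p = 0.0492, adjusted p = 0.483 with an estimated correlation). SNRPN rose by 0.95 and PLAGL1 (-2.37), L3MBTL1 (-1.36) and NAP1L5 (-1.69, on 30 effective fragments or fewer in each library) fell. The imprinted call was lost without naive male 2 (adjusted p = 0.0563), without naive female 1 (0.0828), without primed 2 (0.108), and without both male naive libraries (0.0606). Markers of other cell types were not called as lists: fibroblast and feeder 0 higher and 0 lower of 19 (adjusted p = 0.944), mesoderm and primitive streak 2 (KDR and EOMES) and 0 of 10 (0.0568), endoderm 0 and 1 of 15 (0.613), trophoblast and amnion 3 and 0 of 10 (0.125) and germ cell 2 and 0 of 6 (0.191).

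Under the limits given for SPP1, the 10 largest rises also held CXCL14 (4.22), SFN (3.69), EPHA1 (3.68) and PLAU (3.33), and the 10 largest falls MEOX1 (-3.83), MDGA1 (-3.82), CRYBB1 (-3.75), FGF3 (-3.63) and MEIS2 (-3.44). Some rises rested on few effective fragments in primed libraries: 0 and 6 for CXCL14, 3 and 4 for SFN, 1.4 and 6.8 for SPRY4 and 4 and 11 for FOSL1. In male naive libraries CXCL14 had 17 and 13 and FOSL1 6 and 9. NR5A2 of the naive-associated list had 4.1 and 4 in primed and 13.4 and 18.3 in male naive libraries. Of the 10 falls, 3 were small RNA rows (U6atac, SNORA72 and SNORA63) that were listed at 0 in both male naive libraries and rested on 1 to 9 effective fragments in primed libraries.

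Over all genes, limma called 1548 of 13685 at an adjusted p under 0.05, 920 higher and 628 lower in naive lines, and 4235 at an unadjusted p under 0.05. Upper-quartile scaling gave 693 higher and 878 lower. The count was 625 without both male naive libraries, 516 with all libraries thinned to the lowest total, 941 with no filter and 250 with sex ignored. It was 266 without naive male 1, 261 without naive male 2, 463 without naive female 1, 305 without naive female 2 and 177 without primed 1.

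**Figure D1:**
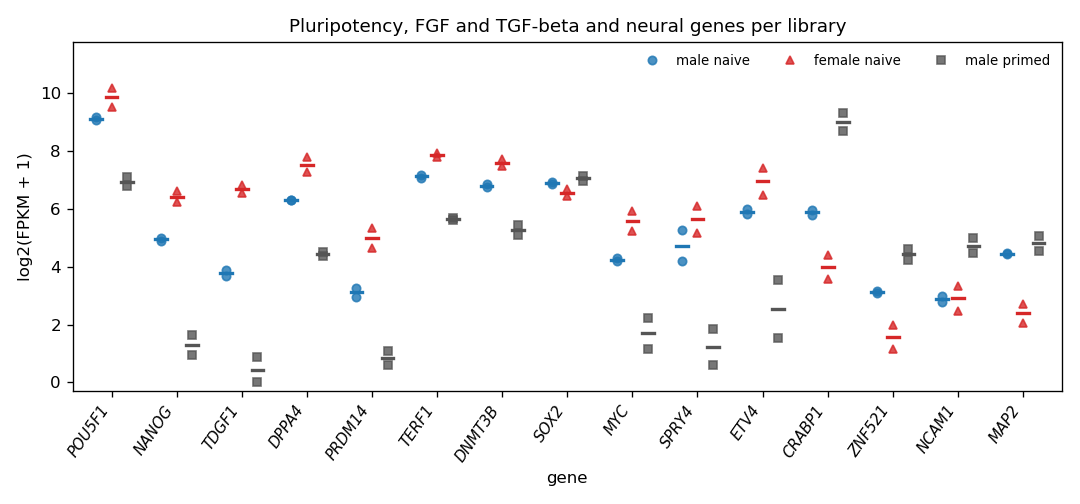
Expression of named genes in the 6 libraries, as log2(FPKM + 1) on the vertical axis, with a symbol per library and a bar at the group mean; male naive, female naive and male primed lines are blue circles, red triangles and grey squares. The genes were taken from those the naming rule gave. NANOG lies at 1.51 FPKM on average in primed lines and at 29.7 and 84.9 in male and female naive lines, CRABP1 at 521 against 57.7 and 15.6, and SOX2 shows no called difference.

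The comparison within males sets male naive against male primed lines and so leaves out sex. POU5F1 rose by 2.18 (SE 0.23, adjusted p = 0.00846), NANOG by 3.65 (SE 0.26, adjusted p = 0.00303) and TDGF1 by 3.35 (SE 0.3, adjusted p = 0.00512). TDGF1 rested on few effective fragments here, 15 and 11 in male naive and 0 and 4 in primed libraries. SPP1 rose by 4.7 (SE 0.49, adjusted p = 0.00836) and CRABP1 fell by 3.12 (SE 0.32, adjusted p = 0.00832). DNMT3B, a de novo DNA methyltransferase of the primed-associated list, was at 111 ± 4.86 FPKM in male naive and 37.6 ± 6.04 in primed lines and rose by 1.54 (SE 0.16). ZIC2, a primed-state transcription factor, fell by 0.7 (SE 0.14, adjusted p = 0.0486), while DUSP6 (0.9, adjusted p = 0.0541) and OTX2 (2.84, adjusted p = 0.173) were not called.

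Among lists, general pluripotency had 9 of 19 members higher and 0 lower (12 and 0 adjusted over the list alone; median 1.56, adjusted p = 7.26e-06, adjusted p = 0.377 with an estimated correlation). FGF and ERK targets had 6 higher and 0 lower of 19 (13 and 1 adjusted over the list alone; median 1.22, adjusted p = 2.67e-05, adjusted p = 0.485 with an estimated correlation), with ETV5 at 2.86 (SE 0.5). Nodal and TGF-beta had 6 higher and 0 lower of 19 (8 and 0 adjusted over the list alone; median 0.91, adjusted p = 0.00242, adjusted p = 0.377 with an estimated correlation). Mesoderm and primitive streak had 1 higher and 0 lower of 10 (5 and 0 adjusted over the list alone; median 1.26, adjusted p = 0.0114, adjusted p = 0.576 with an estimated correlation). Its called member was EOMES, a T-box factor, at 11.7 ± 1.89 FPKM in male naive and 0.224 ± 0.238 in primed lines. The neural list was not called in this contrast (0 higher and 2 lower of 12, adjusted p = 0.0863).

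Small RNA rows again took places among the largest changes: 5S_rRNA, SNORA33, SNORA71 and SNORA18 among the rises, on 3 effective fragments or fewer, and SNORA63, U6atac, SNORA72 and 2 rows named SNORA57 among the falls. Limma called 738 genes, 543 higher and 195 lower in male naive lines, and 3523 at an unadjusted p under 0.05. Rows spanning under 1500 bp made up 38.2% of the calls and 11.7% of the tested rows. Higher calls numbered 391 against 357 lower with upper-quartile scaling, 399 against 294 with quantile normalization and 418 against 255 with median-of-ratios scaling. The count was 464 without rows under 1500 bp, 228 with precision weights, 169 after thinning, 400 with no filter and 348 in a fit to the compared groups alone. It was 86 without naive male 1, 51 without naive male 2, 352 without naive female 1, 330 without naive female 2 and 264 without primed 1.

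Female naive lines, compared with male naive lines in the same medium, had lower levels of 3 of 22 WNT targets and 4 of 18 cholesterol genes and higher levels of 5 of 19 pluripotency genes. SP5 (ENSMMUG00000002690, chromosome 12, 34392144 to 34394780), a transcription factor induced by beta-catenin, was at 1.56 ± 1.56 FPKM in female naive, 44.7 ± 1.29 in male naive and 40.9 ± 25.7 in primed lines. AXIN2, a negative-feedback WNT target, was at 4.36 ± 1.3, 34.1 ± 0.352 and 52.8 ± 33.4 FPKM in the same order. TDGF1 went the other way, at 102 ± 12.6 FPKM in female naive, 12.8 ± 1.19 in male naive and 0.409 ± 0.578 in primed lines. No female primed lines were analysed here, so this contrast does not test whether the naive against primed difference depends on sex.

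WNT and beta-catenin targets had 1 member higher and 3 lower of 22 (3 and 9 adjusted over the list alone; median -1.11, adjusted p = 0.025, adjusted p = 0.518 with an estimated correlation). SP5 fell by 4.31 (SE 0.56, adjusted p = 0.0169), AXIN2 by 2.73 (SE 0.43, adjusted p = 0.0341) and SP8 by 1.76 (SE 0.31, adjusted p = 0.0399), and the receptor FZD7 rose by 0.81 (SE 0.13, adjusted p = 0.0375). Without naive female 2 the adjusted p of the list was 0.097. Cholesterol synthesis had 0 higher and 4 lower of 18 (0 and 7 adjusted over the list alone; median -0.53, adjusted p = 0.000831, adjusted p = 0.504 with an estimated correlation), and among these DHCR7 fell by 0.99 (SE 0.15), LSS by 0.89 (SE 0.14) and SQLE by 0.76 (SE 0.13). General pluripotency had 5 higher and 0 lower of 19 (8 and 1 adjusted over the list alone; median 0.73, adjusted p = 0.000831, adjusted p = 0.504 with an estimated correlation), with TDGF1 at 2.9 (SE 0.3), PRDM14 at 1.89 (SE 0.31), DPPA4 at 1.21 (SE 0.19) and NANOG at 1.47 (SE 0.26). Its median was 0.389 without naive male 2. Neural and ectoderm had 0 higher and 3 lower of 12 (0 and 6 adjusted over the list alone; median -1.01, adjusted p = 0.0215, adjusted p = 0.504 with an estimated correlation): MAP2 fell by 2.06, CRABP1 by 1.88 and TUBB3 by 1.93. Its median was -0.566 without naive female 2.

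Other list calls in this contrast rested on few called members. Reprogramming factors had 1 higher and 0 lower of 5 (3 and 0 adjusted over the list alone; adjusted p = 0.025, adjusted p = 0.504 with an estimated correlation), lost without naive male 1 (0.0733) and naive female 2 (0.0863). The glycolysis list was called with 0 members called of 19 (0 and 0 adjusted over the list alone; median 0.16, adjusted p = 0.025, adjusted p = 0.64 with an estimated correlation), lost without naive female 2 (0.106). The unfolded protein and ATF4 response had 0 higher and 1 lower of 19 (0 and 4 adjusted over the list alone; median -0.43, adjusted p = 0.0388, adjusted p = 0.504 with an estimated correlation), lost without naive male 1 (0.121) and naive female 1 (0.123). Its called member was PSAT1, a serine synthesis enzyme (-1.46, SE 0.11, adjusted p = 0.00345). Nodal and TGF-beta had 1 higher and 1 lower of 19 (3 and 1 adjusted over the list alone; median 0.12, adjusted p = 0.0435, adjusted p = 0.504 with an estimated correlation), with TDGF1 higher and FST lower (-1.8, SE 0.16). This call was lost without naive male 1 (0.142) and naive female 1 (0.0567, median -0.003) and with quantile normalization (0.0949), and the median was 0.193 without naive male 2 and 0.211 without naive female 2. The naive-associated list had 0 called members of 13 (2 and 0 adjusted over the list alone; median 0.35, adjusted p = 0.0457, adjusted p = 0.504 with an estimated correlation). It was lost without naive male 1 (0.135, median 0.195), naive female 1 (0.0567) and naive female 2 (0.081, median 0.023) and with quantile normalization (0.128). The germ cell list had 1 higher and 0 lower of 6 (2 and 0 adjusted over the list alone; median 0.25, adjusted p = 0.0482, adjusted p = 0.504 with an estimated correlation). It was lost without naive male 1 (0.169, median 0.133), naive female 1 (0.371, median -0.15), primed 1 (0.0611) and primed 2 (0.0611) and with quantile normalization (0.108), and the median was 1.027 without naive female 2. The fibroblast and feeder list had 0 higher and 1 lower of 19 (adjusted p = 0.673), the 1 being ACTA2, smooth muscle actin.

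Over all genes limma called 453, 104 higher and 349 lower in female naive lines, and 2963 at an unadjusted p under 0.05. Of the 349 falls, 191 were rows spanning under 1500 bp. Quantile normalization gave 118 higher and 223 lower and median-of-ratios scaling 114 and 219. The count was 183 without rows under 1500 bp, 143 with precision weights, 123 after thinning and 268 with no filter. It was 46 without naive male 1, 41 without naive male 2, 68 without naive female 1 and 54 without naive female 2.

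**Figure D2:**
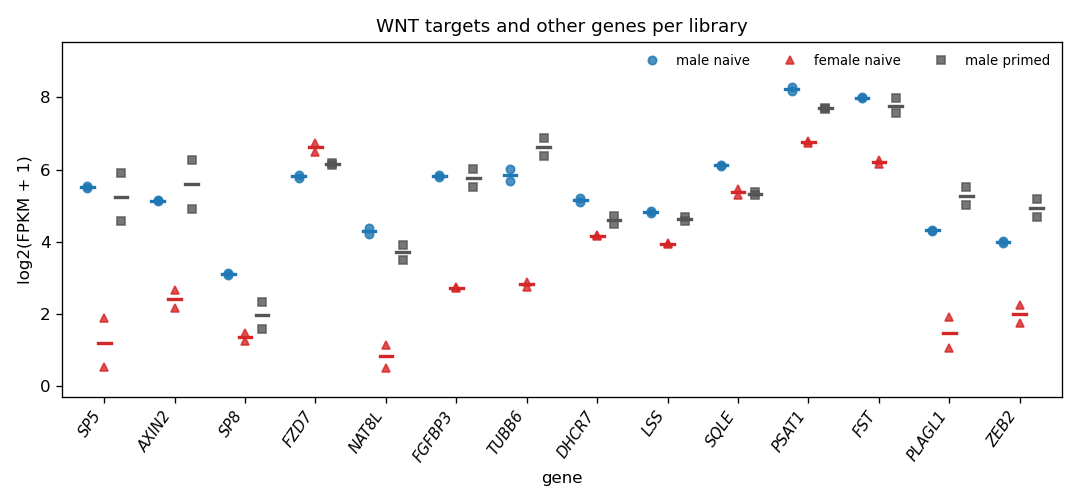
Expression of named genes of the female against male naive comparison in the 6 libraries, as log2(FPKM + 1), with symbols and bars as in the plot of pluripotency genes. The genes were taken from those the naming rule gave. SP5 and AXIN2 average 44.7 and 34.1 FPKM in male naive lines and 1.56 and 4.36 in female naive lines, and the primed lines spread widely in these genes (SD 25.7 and 33.4).

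**Figure D3:**
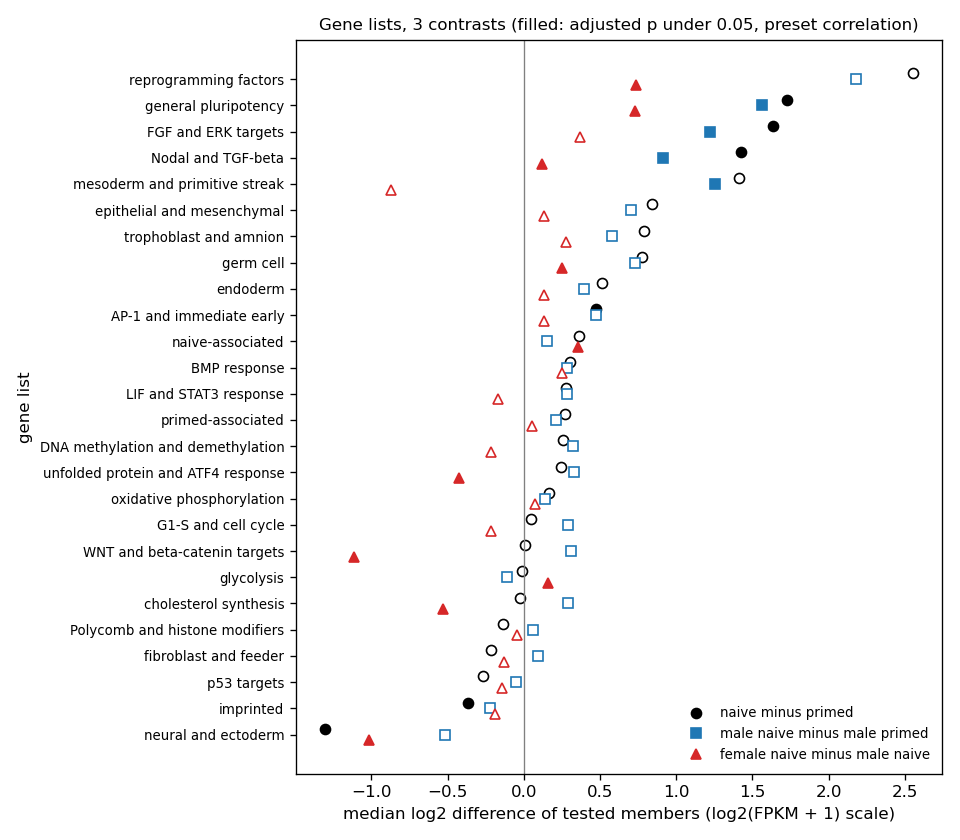
Median log2 difference of the tested members of the 26 gene lists (horizontal axis) in the 3 comparisons, with filled symbols where the camera adjusted p with the preset correlation was under 0.05. Of these lists 6, 4 and 10 were called in naive against primed, male naive against male primed and female against male naive lines, and 0, 0 and 0 with an estimated correlation.

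X-linked genes were compared because the naive lines were of both sexes. The 530 tested X-linked genes had a median log2 difference, female minus male naive, of -0.115, against -0.104 for the 12718 autosomal genes, a difference of -0.011. As a set they were not called (adjusted p = 0.894 over 21 chromosome sets, adjusted p = 0.89 with an estimated correlation). Of them 10 were called higher and 18 lower, against 104 higher and 349 lower over all tested rows. Several of the 18 had no symbol. Some, such as SNRPD2 (chosen after its values were seen), were high only in male naive libraries. It was at 104 and 100 FPKM there, 41.6 and 41.6 in female naive and 47.3 and 47.1 in primed libraries. Others, such as TMSB15A, were also high in primed libraries. The median X-linked minus autosomal level per library was -0.227 and -0.281 in male naive, -0.348 and -0.276 in female naive and -0.312 and -0.25 in primed lines. The files used here hold no row named XIST, JPX, FTX or TSIX, so XIST gave no check of the sex labels. The Y-linked list matched 2 rows, EIF1AY and RPS4Y2, both placed on X, and gave none either.

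**Figure D4:**
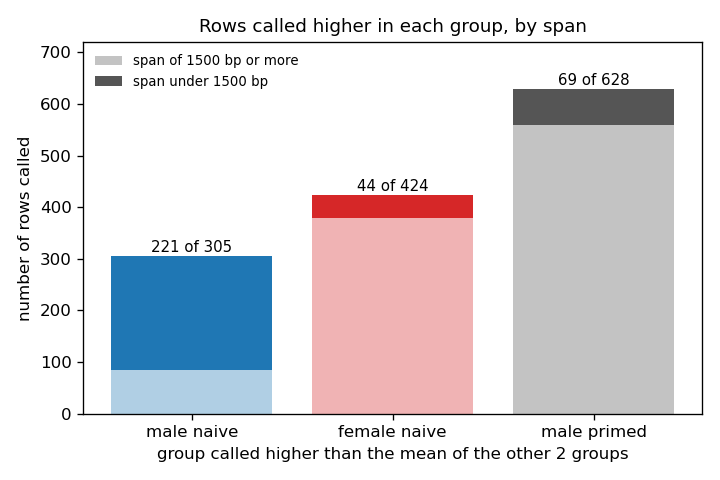
Number of rows called higher in each group than in the mean of the other 2 groups (vertical axis), with rows spanning under 1500 bp in the darker part of each bar. Such rows were 221 of 305 for male naive, 44 of 424 for female naive and 69 of 628 for primed lines.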

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

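The tests of explanations in this part were all chosen after the results were seen, while the comparison of female with male naive lines was fixed before the data were examined. That comparison called 453 genes. It equals the difference between the 2 naive groups when each is set against the same male primed lines, and with no female primed lines analysed here it does not test whether the naive against primed difference depends on sex. Among lists called in naive against primed, general pluripotency (5 higher and 0 lower of 19) differed between female and male naive lines by a median of 0.733 on the log2 scale (adjusted p = 0.000831), neural and ectoderm (0 and 3 of 12) by -1.013 (0.0215) and Nodal and TGF-beta (1 and 1 of 19) by 0.123 (0.0435). All 3 calls were lost with an estimated correlation (adjusted p = 0.504 for each). The medians were 0.389 for pluripotency without naive male 2 and -0.566 for neural and ectoderm without naive female 2. For Nodal the median was -0.003 without naive female 1, 0.193 without naive male 2 and 0.211 without naive female 2, and its call was lost without naive female 1 (0.0567) and naive male 1 (0.142). Genes named in the text that were called against primed lines and also differed between the naive sexes were higher in female naive lines for TDGF1 (2.9), PRDM14 (1.89), KDR (1.86), NANOG (1.47), DPPA4 (1.21) and TERF1 (0.74). They were lower in female naive lines for PLAGL1 (-2.85), AXIN2 (-2.73), MAP2 (-2.06), ZEB2 (-1.99), CRABP1 (-1.88), FST (-1.8), EPHA4 (-1.75), COL2A1 (-1.54), PSAT1 (-1.46), VIM (-1.06) and SQLE (-0.76).

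The called pluripotency genes were lower in both primed libraries than in all 4 naive libraries. Low depth of the male naive libraries is argued against by the female naive minus primed median of 2.03 (median SE 0.3), taken between libraries of similar depth. Dilution of the primed cultures is argued against only as the sole cause and only for cells that lack all these transcripts, which would lower all members alike. The log2 ratios of 8 called members with 20 or more fragments, naive sexes pooled, had an SD of 1.12 (median SE 0.23). They ran from 1.91 for TERF1 to 5.25 for NANOG, with POU5F1 at 2.62 and DPPA4 at 2.67. The ratios are of mean FPKM, while the SE is on the log2(FPKM + 1) scale. Cells that express some of the members would lower them unequally, and dilution by such cells is not covered. Neural and ectoderm markers were lower in naive than in primed lines, with 5 of 12 called (median -1.30), and dilution by neural or ectoderm cells was not tested. Fibroblast markers, chosen after their values were seen, differed between the primed libraries. COL1A1 was at 9.23 FPKM in primed 1 and 135 in primed 2 against 42 to 153 in naive libraries. FN1, LUM and COL3A1 were higher in primed 2 than in any naive library, while FN1 and COL3A1 were lower in primed 1 than in any. Dilution as a part of the difference stays open. The difference in state or medium stays open as a hypothesis, and medium and state cannot be separated in this design.

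Of 22 WNT targets 3 were lower and 1 higher in female than in male naive libraries (adjusted p = 0.025, adjusted p = 0.518 with an estimated correlation, 0.097 without naive female 2). The list median was -1.13 after thinning all libraries to the lowest total and -1.11 before (median SE 0.42), so the difference stayed at equal depth. Thinning keeps the expected FPKM and adds only counting noise. It therefore cannot tell low depth of the male naive libraries apart from other causes. Variation between lines cannot be told apart from sex: members differed between the 2 primed lines by a median of 1.02 and between the naive sexes by 1.28, with 0.18 and 0.4 between lines within male and female naive groups, and each sex has 2 lines. Sex and donor stay open and untested.

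Rows spanning under 1500 bp made up 72.5% of the rows called higher in male naive libraries than in the other groups, against 10.4% for female naive and 11% for primed. Rows with a mean of 100 or more effective fragments over the 6 libraries, called or not, were 346 short and 7867 longer rows. In male naive libraries 46 of the short (13.3%) and 57 of the longer rows (0.72%) were called higher, so the excess was not limited to rows with few fragments. The test chosen for few fragments was the median difference of male naive from the other groups. In it the short rows as a whole lay only 0.15 (median SE 0.15) above the longer ones, which cannot decide the question. Of all 221 short rows called higher, 109 had a mean of fewer than 20 fragments in male naive libraries. For those 109 few fragments cannot be told apart from other causes. Reads shared with near-identical copies cannot be told apart from other causes, since 14.5% of the short rows called higher and 20% of other short rows carried the FPKM of another row in naive male 1, the 1 library looked at, and no sequence was used here. A library or read-length difference may account for the pattern (72.5%), but it is confounded with the male naive group, as is any biological difference of these lines.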

How the results depend on the processing

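The alternatives with precision weights, fragment or span filters, thinning, both male naive libraries left out and crossed numbers were chosen after seeing the data, and all others before the data were examined. Counts of called genes were 1548, 738 and 453 in naive against primed, male naive against male primed and female against male naive lines. They became 941, 400 and 268 with no filter and 516, 169 and 123 with libraries thinned, where fewer fragments leave less precision. Precision weights gave 228 and 143 in the last 2 comparisons, and leaving out rows under 1500 bp 464 and 183. Naive against primed gave 250 with sex ignored, 625 without both male naive libraries and 890 at a log2 difference of 1 or more, and male naive against male primed 348 in a fit to the compared groups. Leaving out 1 library gave 177 to 1081, 51 to 626 and 41 to 523 genes, the lone library of a group being assumed to vary like the others. The lowest came without primed 1 (177) and without naive male 2 (51 and 41). The cause of these moves was not tested, except that fewer libraries, rows or fragments were used by construction. Apart from the replicate block and crossed numbers, given next, the remaining alternatives stayed within 1.5 times each count, with 1223 to 1769, 588 to 842 and 325 to 505 genes.

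Numbers in the titles did not pair the libraries: deviations of same-numbered libraries correlated at -0.05, -0.263 and -0.06. With the number as a replicate block the counts were 812, 373 and 207. With the female naive numbers crossed they were 1270, 593 and 298.

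With an estimated correlation 0, 0 and 0 lists were called in place of 6, 4 and 10. Leaving out 1 library gave 5 to 9, 4 to 7 and 5 to 10 lists. Male naive against male primed had 7 without primed 1 and 7 without primed 2, and female against male naive had 5 without naive male 1 and 6 without naive female 1. Of 20 list calls, quantile normalization ended 3 (Nodal, naive-associated and germ cell in female against male naive) and the replicate block 1 (imprinted in naive against primed, adjusted p = 0.0701), and 0 reversed. The difference of X-linked from autosomal medians ran from -0.037 to 0.009 when 1 library was left out, with 0.009 without naive male 1, and was not called. The lowest r within a group (0.95) became 0.907 and the highest between groups (0.921) 0.883 with pseudocount 0.1. No named called gene reversed in any of these alternatives. With 1 library left out, 27 to 59 of 79 such genes kept their call in naive against primed, 8 to 35 of 52 in male naive against male primed and 7 to 44 of 47 in female against male naive. The fewest were kept without primed 1 (27), without naive male 2 (8), and without naive male 1 or naive male 2 (7 in either case). Scaling moved the median log2 difference of all genes from 0.090 to -0.057 in male naive against male primed (upper-quartile) and from -0.104 to 0.029 in female against male naive (median-of-ratios). Keeping the highest row in place of a sum was not run, since each identifier has 1 row. Depth limits the male naive libraries most, and calls resting on under 20 effective fragments numbered 174, 163 and 126.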

Other observations

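Among groups the report did not describe, 3 of 16 DNA methylation genes rose in naive lines and 0 fell (4 and 0 adjusted over the list alone), and the list was not called (adjusted p = 0.128). DNMT3B rose by 1.94 (SE 0.14), ZFP57, an imprint-protecting zinc finger, by 1.19 (SE 0.17) and DNMT3A by 0.77 (SE 0.15). Epithelial and mesenchymal genes had 4 higher and 2 lower of 20 (9 and 4 adjusted over the list alone; adjusted p = 0.0568). The epithelial splicing regulators ESRP1 (2.45, SE 0.34) and ESRP2 (1.96, SE 0.24) and the tight-junction gene CLDN6 (1.31, SE 0.13) rose, and ZEB2 (-1.93, SE 0.22) and VIM (-0.99, SE 0.15) fell. BMP response had 3 higher and 0 lower of 14 (5 and 2 adjusted over the list alone; adjusted p = 0.59), with BMP4 at 1.95 (SE 0.23). Primed-associated genes had 5 higher and 3 lower of 21 (9 and 6 adjusted over the list alone; adjusted p = 0.59), with COL2A1 at -2.02 (SE 0.23).

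Metabolic and growth lists moved little in naive against primed lines. Oxidative phosphorylation had 1 higher and 0 lower of 43 (adjusted p = 0.125), glycolysis 1 higher and 3 lower of 19 (0.903), cholesterol synthesis 1 and 1 of 18 (0.703), G1-S and cell cycle 0 and 0 of 26 (0.703), p53 targets 1 and 1 of 20 (0.385), the unfolded protein and ATF4 response 1 and 1 of 19 (0.738) and Polycomb and histone modifiers 1 and 1 of 19 (0.59). Within these lists SLC16A1, a lactate transporter, rose by 1.02 (SE 0.12), and HK2 (-0.76, SE 0.17) and DDIT4 (-2.32, SE 0.25) fell. LIF and STAT3 response had 3 higher and 0 lower of 18 (0.59), WNT and beta-catenin targets 1 and 1 of 22 (0.59) and reprogramming factors 3 and 0 of 5 (0.133). Median, mean and test differed in sign for 4 lists in this comparison: fibroblast and feeder (-0.215, 0.004, lower), glycolysis (-0.009, 0.073, lower), WNT and beta-catenin targets (0.011, -0.147, lower) and the unfolded protein and ATF4 response (0.247, -0.026, higher). In male naive against male primed they differed for fibroblast and feeder (0.096, -0.021, lower) and Polycomb (0.058, -0.025, lower). In female against male naive they differed for DNA methylation (-0.214, 0.006, higher), fibroblast and feeder (-0.13, 0.049, higher), LIF and STAT3 response (-0.172, 0.014, higher), Polycomb (-0.047, -0.03, higher) and primed-associated genes (0.055, -0.005, higher).

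The 2 primed lines differed from each other in fibroblast markers chosen after their values were seen. COL1A1 was at 9.23 FPKM in primed 1 and 135 in primed 2, FN1 at 39.3 and 354, LUM at 0.111 and 19.9 and COL3A1 at 0.414 and 28.6. Naive libraries ranged between 42 and 153 FPKM for COL1A1, 42.9 and 272 for FN1, 0.0739 and 3.85 for LUM and 4.64 and 7.001 for COL3A1.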
